A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

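Gene expression was measured by RNA sequencing of total RNA in 8 libraries. Per the labels, 6 libraries came from bone marrow cells of wild-type C57BL/6 mice: 3 from macrophages grown with 50 ng/ml M-CSF, the growth factor of the macrophage lineage, and 3 from osteoclasts grown with 50 ng/ml M-CSF and 100 ng/ml RANKL, the cytokine that drives osteoclast formation. The other 2 libraries came from MDA-MB-231 human breast cancer cells kept for 3 days in DMSO or in 40 µM olaparib. A strand-specific library kit used with 1 µg of total RNA is stated for the MDA-MB-231 cells; the strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart. Groups were taken from the treatment labels (human) and from the cell type given as the sample source (mouse).

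The deposited values are counts per gene symbol in 1 table per species, with 25668 symbols for mouse and 25611 for human. STAR 2.6.0c, featureCounts 1.6.2 and the builds mm10 and hg19 are listed in the submitters' processing notes, with no role or order. The deposited tables are named as normalized, but the values look like raw counts. They are whole numbers whose totals differ between libraries. The whole numbers from 1 to 60 were filled evenly: the deviation from a smooth curve (chi-square per degree of freedom) was 0.81 to 1.36 over the 8 libraries. Lowering or raising the same counts by 3% and rounding gave 1.99 to 3.42 and 2.86 to 4.46. The values were therefore analysed as counts, and the test planned for normalized values was replaced by the count test that had been set for this case. For the human libraries, TMM scaling likewise replaced the deposited scale that had been planned, and the deposited scale was run as an alternative.

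Mouse genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, group as the only term), two-sided, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p below 0.05. A gene is said to have risen or fallen only if it passed this test; standard errors were taken from the fold change and its F statistic. Levels are TMM-scaled counts at a common library size (CPM, edgeR's cpm function). Gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists that had at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Adjusted p-values of single genes come from edgeR's quasi-likelihood test, and those of lists from camera. On counts simulated from the means and library sizes of these 6 libraries (13051 genes tested), the gene test recovered 26% of genes changed by 0.25 log2, 62% at 0.5, 79.2% at 1 and 100% at 2, and 9.2% of its calls were false. Only 46 to 50 tested genes were changed at each size, a far smaller share than was called in the real libraries. These rates therefore need not hold there. A list raised by 0.5 log2 was called and 0 of 19 unchanged lists were. Genes were simulated independently, so false list calls from correlation between genes could not show. In the real libraries the estimated correlation was 0.552 for the oxidative phosphorylation list.

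The human groups held 1 library each, so no test was made and no p-value is given. Ratios are log2 of olaparib over DMSO on TMM-scaled counts with a pseudocount of 1, ranked for genes with a mean of at least 50. A gene passed the size rule at a ratio of at least 1 in absolute value. Intervals of single ratios are exact conditional binomial intervals at 95% and cover counting error only, as do the floors. The median ratio of each list, over members with a mean of at least 10, was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the 1st or above the 99th percentile. In simulated libraries (10266 genes ranked), 0% of genes changed by 0.5 log2 passed the size rule, 46% at 1, 98% at 1.5 and 100% at 2, with 0 unchanged genes. A list shifted by 0.5 stood apart and 0 of 20 unchanged lists did. Only counting error was simulated, with no further spread between libraries and no trend with GC content or length. False passes in the real pair were therefore not measured.

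Genes to be named were set by a rule written before the data were examined: key genes chosen for the study's subject, the 12 most raised and 12 most lowered genes with a mean of at least 50 (in mouse, also past the test and with groups that do not overlap), the up to 4 members of each list that changed most, and any member of the glutamine lists. Other list members are named as further examples, chosen after their values were seen. The results of some genes and lists are not reported here. The lists covered osteoclast and macrophage function, antigen presentation, interferon and inflammatory genes, glutamine, glutathione and central carbon metabolism, cell cycle, DNA repair, and markers of other cell types. Where a group had a summed count of 0, a fold is a lower bound against 3 counts over the group; with 1 to 3 counts the ratio is given with its 95% counting interval.

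Coordinates are 1-based gene spans of GENCODE M21 on mm10, which held 99.2% of the mouse symbols. The 23 mouse symbols that a spreadsheet had turned into dates were not named. Genes with near-identical copies (Stfa3, Hspa1a, Hspa1b, CST1, HSP90AA2P, histone and HLA genes) are uncertain, since reads could be split between copies. A human annotation was not used here: GC content and length of human genes were taken from the longest coding transcript of the mouse gene of the same name, found for 87.9% of the 10280 ranked genes. Alternatives were other filters, scalings (deposited scale, equal totals, median of ratios, quantile normalization), pseudocounts, limma and DESeq2 1.42.0, a replicate block, leaving out each library in turn, and, chosen only after the data were seen, leaving out ribosomal RNA-like features, leaving out macrophage library 1 together with osteoclast library 2, matching human lists also on GC content and length, quantile normalization for the human lists, and removing the GC and length trend from the human ratios. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.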

Results

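The data cover the cells that resorb bone and a breast cancer line exposed to a PARP inhibitor. The mouse set held 3 libraries of bone marrow macrophages and 3 libraries of osteoclasts, the multinucleated cells formed from such macrophages under RANKL. Total counts ran from 16743849 to 22587509 per mouse library, which puts the floor of 3 counts at 0.133 to 0.179 CPM (counts scaled to a common library size). The human set held 1 DMSO and 1 olaparib library of MDA-MB-231, an established triple-negative breast cancer line; olaparib inhibits the DNA repair enzymes PARP1 and PARP2. These libraries held 7472981 and 6878212 counts, with floors of 0.401 and 0.436 CPM. The labels do not say whether mouse replicates came from separate animals or cultures, so p-values measure only the spread between these 6 libraries, which may be technical.

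The first comparison asks what changes when marrow macrophages become osteoclasts, in a series whose title links glutamine of the bone stroma to PARP inhibitor resistance of tumour cells. Osteoclasts gained the bone-resorbing machinery. Mmp9, a gelatinase that degrades bone matrix, rose from 1.94 ± 0.245 to 8477 ± 307 CPM (mean ± SD, n = 3 per group). Acp5, the tartrate-resistant acid phosphatase that marks osteoclasts, rose from 2.94 ± 0.118 to 1370 ± 55.3 CPM, and Ctsk, the collagen-degrading cathepsin K, from 5.02 ± 2.05 to 1774 ± 50.0 CPM. Osteoclasts also carried more transcript of inflammatory mediators, of the cystine transporter Slc7a11 and of glycolytic and respiratory enzymes, and less of cell cycle genes. With an estimated correlation these lists did not pass (adjusted p = 0.0851 for inflammatory genes, 0.2 for glycolysis, 0.344 for oxidative phosphorylation and 0.304 for cell cycle). Glul, the enzyme that makes glutamine from glutamate, rose from 153.2 ± 3.55 to 275.8 ± 7.46 CPM.

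Of 13247 genes tested, 4281 rose and 4162 fell in osteoclasts, 1238 and 875 of them by at least 1 log2, and 4804 did not pass. The groups did not overlap for 9021 genes (68.1%; chance gives 10%), and the first principal component, 88.1% of the variance, separated them. The balance of directions depends on scaling: 50.7% of calls were higher with TMM, against 28.9% (2625 higher, 6445 lower) with equal totals and 32.2% (1800 higher, 3790 lower) on the deposited scale, which shift the median gene by -0.22 and -0.19 log2. Changes below that size are therefore relative to the typical gene. The deposited scale makes no correction for total counts, so differences in depth within a group add to its spread. Over 10280 mouse genes, the difference between osteoclast and macrophage libraries fell with transcript length (Spearman's rho -0.23). Its rho with GC content was 0.07. The mouse lists were not matched on length, so how far this trend bears on their changes was not tested.

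Among 35 osteoclast differentiation and resorption genes, 28 rose, 4 fell and 3 did not pass, with a median of 2.00 log2 (28 and 4 adjusted over the list alone, 26 and 7 with equal totals). Mmp9 rose by 12.08 log2 (SE 0.085, adjusted p = 1.91e-17), Acp5 by 8.86 (SE 0.072, adjusted p = 3.70e-17) and Ctsk by 8.49 (SE 0.195, adjusted p = 4.43e-13). On mm10, Mmp9 spans chromosome 2 from 164940780 to 164955850 (plus strand), Acp5 chromosome 9 from 22126727 to 22135711 (minus strand) and Ctsk chromosome 3 from 95499256 to 95509362 (plus strand); counts are over whole genes. Calcr, the calcitonin receptor, had 0 counts in macrophages and was at least 320-fold higher in osteoclasts. Car2, the carbonic anhydrase that supplies protons for resorption, had 1 macrophage count and a ratio of 2060 (95% counting interval 369 to 81400). Oscar, a costimulatory receptor of osteoclasts, rose by 9.22 log2 (10.66 without macrophage library 2), the fusion genes Ocstamp and Dcstamp by 6.90 and 4.61, the integrin subunit Itgb3 by 3.73 and the proton pump subunit Atp6v0d2 by 2.13. Nfatc1, the master transcription factor of the lineage, rose by 0.30 (adjusted p = 2.88e-05), a call lost on the deposited scale (0.11) and with equal totals (0.08). The receptor of RANKL, Tnfrsf11a, fell by 0.60, and Trem2, another receptor gene of this list, fell from 719.6 to 359.0 CPM. The list's camera adjusted p was 9.94e-09, and the adjusted p = 0.2 with an estimated correlation. Of 15 V-ATPase subunits, the proton pump of lysosomes and of the resorbing membrane, 13 rose, led by Atp6v0c (1.48), and 1 fell, Atp6v0a1 (-1.01); 14 rose adjusted over the list alone and 7 on the deposited scale (camera adjusted p = 0.000189; adjusted p = 0.344 with an estimated correlation). Of 14 cell fusion genes, 8 rose and 6 fell, the same counts adjusted over the list alone but 5 and 3 on the deposited scale, where the list was called (camera adjusted p = 0.243 with TMM).

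**Figure D1:**
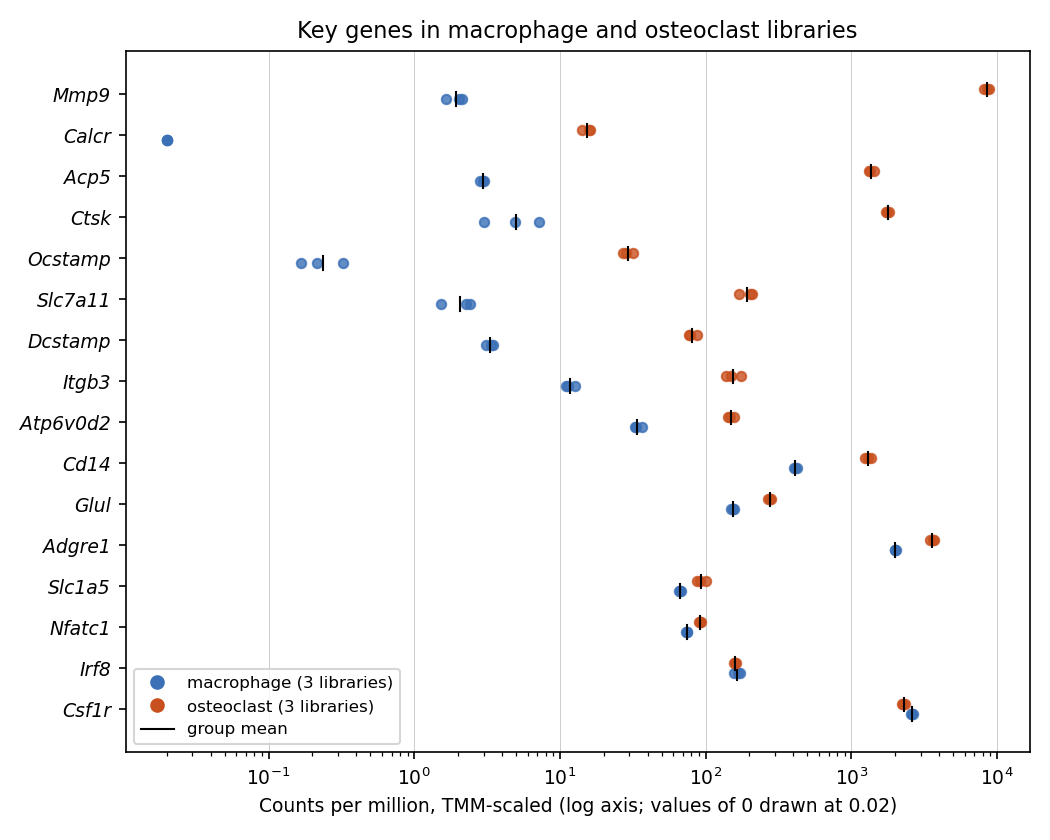
Expression of 16 mouse key genes on a log axis of TMM-scaled CPM, with one point per library (3 macrophage, 3 osteoclast), vertical bars at group means and values of 0 drawn at 0.02. Mmp9 moved from a mean of 1.94 to 8477 CPM and Slc7a11 from 2.06 to 192.7 CPM.

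Macrophage genes split. Of 28 identity genes, 12 rose and 16 fell (the same adjusted over the list alone); the median was -0.40, the mean 0.24, and camera gave no call (adjusted p = 0.592). The scavenger receptor Marco rose by 10.43 log2 and the lectin Clec4n by 5.79. Cd14, the lipopolysaccharide co-receptor, rose by 1.66 and Adgre1, which encodes F4/80, by 0.84. Axl, a receptor for dying cells (-5.61), and the chemokine receptor Ccr2 (-4.91) fell. The M-CSF receptor Csf1r fell by 0.19 (adjusted p = 0.00139), a call lost on the deposited scale (-0.38, adjusted p = 0.087). Of 13 negative regulators of osteoclast formation, 5 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.592): Socs3, an inhibitor of cytokine signalling, rose by 4.67 and Cebpb by 2.06, while Id1 fell by 1.47. Pparg, a nuclear receptor of lipid metabolism on the same list, fell by 4.10. Irf8, a repressor of the osteoclast programme, changed by -0.06 (adjusted p = 0.192; with equal totals -0.28, past the threshold).

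Inflammatory genes rose as a group. Of 21 cytokine, chemokine and mediator genes, 20 rose and 1 fell, with a median of 2.78 log2 and the same counts adjusted over the list alone (camera adjusted p = 8.93e-10; adjusted p = 0.0851 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose by 11.26 (SE 0.085, adjusted p = 2.24e-17), from 0.178 ± 0.0417 to 445.4 ± 15.9 CPM. The arginine-degrading enzyme Arg1 rose by 7.66, Il1a by 5.35, the chemokine Ccl5 by 4.71 and Il1b by 4.67, and Il10, an anti-inflammatory cytokine, fell by 1.57. Of 25 interferon-stimulated genes, 19 rose and 2 fell, the same adjusted over the list alone but 10 and 2 on the deposited scale and 14 and 6 with equal totals, led by Gbp2 (1.94), Oasl1 (1.44) and Cxcl10 (1.23) (camera adjusted p = 0.000312; adjusted p = 0.344 with an estimated correlation). Of 14 antigen presentation genes, 10 rose and 2 fell, also adjusted over the list alone: the costimulatory gene Cd80 rose by 2.08 and the class II chain H2-Ab1 by 1.16, and H2-Eb1 fell by 0.53 (camera adjusted p = 0.0158; adjusted p = 0.344 with an estimated correlation; the call was also lost on the deposited scale, where 4 rose and 3 fell, and with equal totals 7 rose and 4 fell). Of 4 tested neutrophil markers, 3 rose: Lcn2, an iron-sequestering antimicrobial protein with 2 macrophage counts (ratio 1631, 95% counting interval 451 to 13480), S100a8 (7.18) and the collagenase Mmp8 (6.39). Csf3r fell by 0.18, a call lost with DESeq2 (-0.17) and on the deposited scale (-0.37). Camera gave an adjusted p of 0.0529 for the list. The list was called on the deposited scale, with equal totals and without any 1 of the macrophage libraries, among 11 settings in all besides fry. S100a9, the usual partner of S100a8, had 0 macrophage counts and 1 osteoclast count.

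Glutamine genes moved unevenly. Slc7a11, which exchanges glutamate for cystine, rose by 6.56 log2 (SE 0.115, adjusted p = 3.63e-14), from 2.06 ± 0.475 to 192.7 ± 19.2 CPM (chromosome 3, 49892526 to 50443614, minus strand). Glul rose by 0.85 (SE 0.035, adjusted p = 1.54e-10; chromosome 1, 153899944 to 153909723, plus strand), and the serine and asparagine synthesis genes Psat1 and Asns by 0.61 and 0.56, of which Asns lost its call on the deposited scale (adjusted p = 0.0696). Slc1a5, the main glutamine importer of many cells, rose by 0.47 (67.0 ± 1.05 to 93.0 ± 6.24 CPM), although on the deposited scale its adjusted p was 0.16. The lysosomal amino acid sensor Slc38a9 fell by 0.50. In all, 11 of 29 tested members rose, 2 fell and 16 did not pass, with the same counts adjusted over the list alone; camera gave an adjusted p of 0.068. The median, 0.10, turned to -0.12 with equal totals (7 rose, 11 fell) and to -0.09 on the deposited scale (3 rose, 2 fell), with 9 and 5 after quantile normalization, and Slc38a2 and Slc3a2, called higher by 0.20 and 0.19, lost those calls there.

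The glutathione and ferroptosis list rose: of 22 genes, 20 rose and 1 fell, with a median of 1.47 (camera adjusted p = 1.37e-08; adjusted p = 0.2 with an estimated correlation; same counts adjusted over the list alone). The quinone reductase Nqo1 rose by 3.93 and glutathione reductase Gsr by 2.88, and the iron exporter Slc40a1 fell by 1.63. Of 21 glycolysis genes, 20 rose and 0 fell, also adjusted over the list alone, with a median of 1.15, among them the lactate dehydrogenase subunit Ldhb (3.73), the glycolytic activator Pfkfb3 (2.47) and the glucose transporter Slc2a1 (1.96) (camera adjusted p = 8.93e-10; adjusted p = 0.2 with an estimated correlation). Of 21 TCA cycle genes, 19 rose and 0 fell, also adjusted over the list alone. On the deposited scale 9 rose and 0 fell, and with equal totals 14 and 1. Idh1 (1.79), whose enzyme is the cytosolic form, and Mdh2 (1.19) led the list (camera adjusted p = 6.11e-07, adjusted p = 0.304 with an estimated correlation). Of 47 oxidative phosphorylation genes, 45 rose, 46 adjusted over the list alone and 21 on the deposited scale, and 0 fell, with a median of 0.55 (0.37 on the deposited scale), led by Uqcrfs1 (57.0 to 121.9 CPM) and Cox8a (78.6 to 168.0 CPM; camera adjusted p = 3.04e-11; adjusted p = 0.344 with an estimated correlation). Mitochondrially encoded transcripts took 2.15 to 2.31% of osteoclast counts and 1.42 to 1.56% of macrophage counts. Of 35 cell cycle and replication genes, 31 fell and 0 rose, also adjusted over the list alone, with a median of -0.63, among them the mitotic genes Cenpf (-1.26) and Kif11 (-1.07), and the proliferation marker Mki67 (-1.01; camera adjusted p = 4.93e-09; adjusted p = 0.304 with an estimated correlation).

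**Figure D2:**
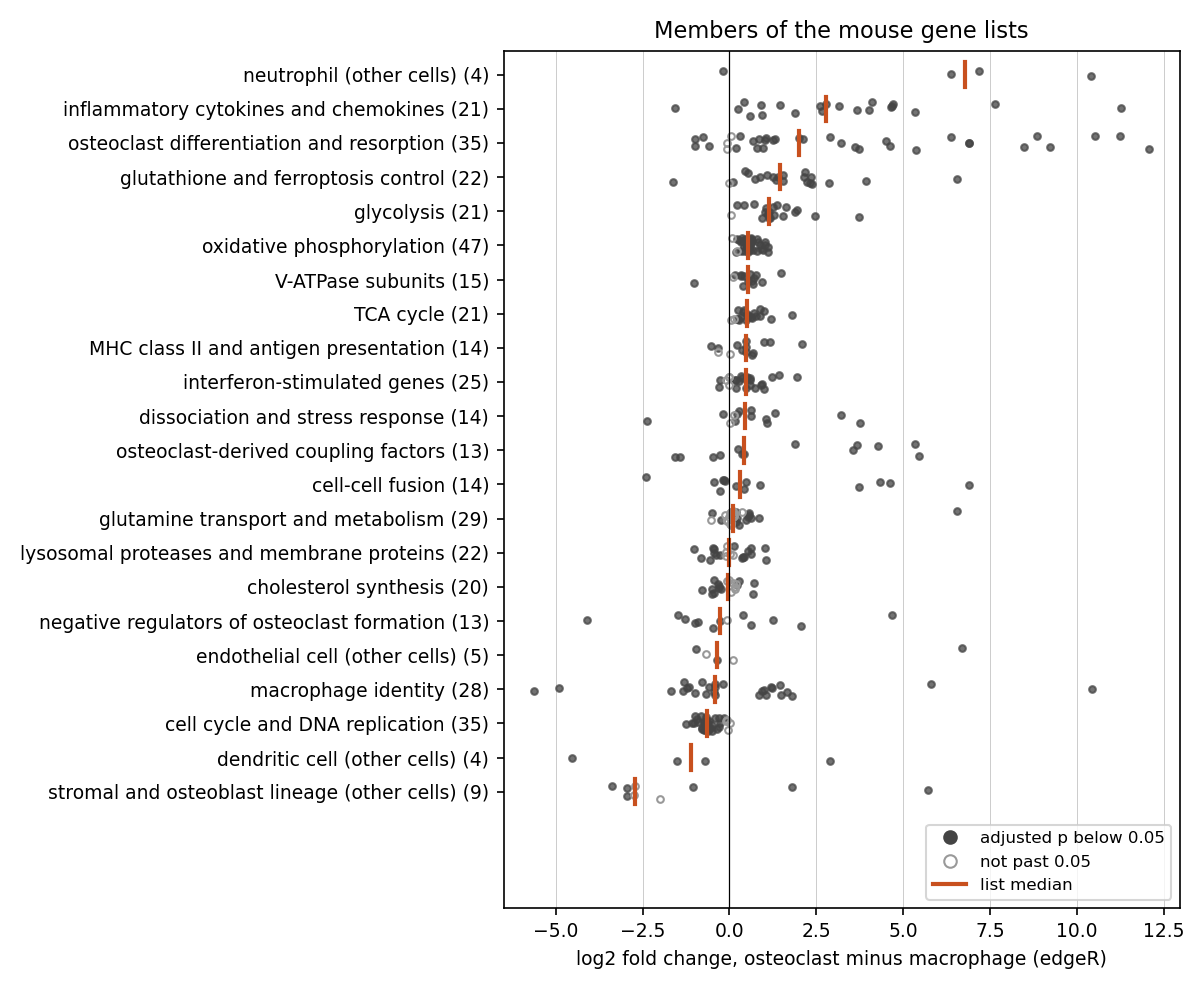
Log2 fold changes (osteoclast minus macrophage) of every tested member of the mouse lists, with filled points for members past an adjusted p of 0.05 and a bar at each list's median. The inflammatory list centres on 2.78 with 20 of 21 members higher, and the cell cycle list on -0.63 with 31 of 35 lower.

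Outside these groups, the most raised genes were Slpi, a secreted protease inhibitor with 5 macrophage counts (11.38 log2, 10.76 to 12.14 when single libraries were left out), and genes with 0 macrophage counts: the vesicle fusion gene Cplx2 (at least 348-fold higher), the cystatin-like Stfa3 (at least 334-fold), Rufy4 (at least 275-fold), the metalloreductase Steap4 (at least 235-fold) and the interleukin-1 family gene Il1f9 (at least 183-fold). The most lowered were Hpgd, which inactivates prostaglandins (-9.54), and the transcription regulator Tox2, whose 3 osteoclast counts give a macrophage to osteoclast ratio of 681 (95% counting interval 233 to 3306). Other strongly lowered genes were the transporter Slco2b1 with 1 osteoclast count (ratio 442, interval 79.0 to 17490), Ctla2a with 3 (ratio 156, interval 53.03 to 758), the sialic acid hydroxylase Cmah (-7.15), Chn2 (-6.89; -7.71 without osteoclast library 1) and the proteoglycan Cspg4 (-6.57). Rhoh (-6.28), the progenitor marker Cd34 (-5.91), Gpr34 (-5.72; -6.94 without osteoclast library 3) and Shisa9 (-5.65) were also among them. Folds of genes with few counts in a group, among them Nos2, Slpi, Hpgd, Ocstamp, S100a8, Il1a, Irf4, Rhoh and Shisa9, were more than 1.5 times smaller with limma and a pseudocount of 5, and still passed the test.

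Individual libraries stood apart. Macrophage library 1 held 489.7 CPM of stromal and osteoblast-lineage transcripts, against 21.93 and 16.03 in the other macrophage libraries and 33.4 to 50.8 in osteoclasts. Of 9 such genes tested, 2 rose and 4 fell, 6 adjusted over the list alone, 7 on the deposited scale and 1 after quantile normalization (camera adjusted p = 0.93). The proteoglycan Dcn rose by 5.71 (without macrophage library 1 the estimate, against 0 macrophage counts, was 10.71), and the collagens Col1a1 (-2.95) and Col1a2 (-2.96) and fibronectin Fn1 (-3.38) were called lower; without that library they were higher at 1.19 and 1.13 for the collagens and not past the test at 0.28 for Fn1, and limma called none of these 3. Osteoclast library 2 held 1.87% ribosomal RNA-like counts (0.024 to 0.12% elsewhere) and 4158 CPM of the nuclear RNA Malat1 (1105 to 1464 elsewhere). Its differences from the other osteoclast libraries exceeded counting error most (chi-square per degree of freedom 32.50 and 36.43, against 2.92 between those libraries). Markers of other marrow cells were few. Of 4 dendritic genes 1 rose and 3 fell (Irf4 -4.53, camera adjusted p = 0.243). The 1 that rose was Zbtb46, by 2.68 to 3.095 when single libraries were left out. Of 5 endothelial genes 1 rose and 2 fell (Kdr -0.95, camera adjusted p = 0.762), with a median of -0.35 and a mean of 0.97. Here Esam rose, by 6.132 to 9.259 when single libraries were left out. Of 2 lymphoid genes 1 fell (Ighm -4.51), and both tested platelet chemokines rose (Ppbp 2.78, Pf4 1.57). Counts for these lists were the same adjusted over the list alone. Of 14 dissociation and stress genes, 10 rose and 2 fell, also adjusted over the list alone, led by the heat shock genes Hspa1b (3.75) and Hspa1a (3.22) (camera adjusted p = 0.00643; adjusted p = 0.304 with an estimated correlation). Osteoclasts and macrophages differed in RANKL and possibly in culture time and medium, which these libraries do not separate. Each library measures the total RNA of a whole sample, so which cells of a sample held a transcript was not resolved.

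The second comparison asks how MDA-MB-231 cells respond to olaparib; with 1 library per condition it compares 2 libraries, with no replicate check. Interferon-stimulated and secreted inflammatory genes were higher in the olaparib library, and DNA repair and mitotic genes lower. ISG15, a ubiquitin-like interferon-induced protein, went from 2869 counts in DMSO to 22229 in olaparib, a log2 ratio of 3.14 (95% counting interval 3.08 to 3.19). CDKN1A, the p21 inhibitor of cell cycle kinases, went from 1007 to 2762 counts (1.64, 1.53 to 1.74), and MKI67, the proliferation marker, from 4044 to 890 (interval -2.11 to -1.90). BRCA1, which directs homologous recombination, went from 274 to 71 counts (-1.75, -2.16 to -1.39). Long, GC-poor transcripts as a whole were lower in the olaparib library, and the repair and mitotic lists did not stand apart from genes of like GC content and length.

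Of 10280 genes ranked, 804 were higher and 2176 lower by at least 1 log2, 53 and 325 of them by at least 2. The share of genes past the size rule that were higher was 27.0% with TMM, 14.2% (448 higher, 2703 lower) on the deposited scale, 20.1% (610 and 2419) with median of ratios and 43.2% (1262 and 1661) with quantile normalization. The median ratio was -0.02 with TMM, -0.21 on the deposited scale, -0.11 with median of ratios and 0.12 with quantile normalization. Across 9035 genes, the ratio followed the GC content of the mouse orthologue's transcript (Spearman's rho 0.65, across genes, which are not independent replicates) and its length (rho -0.51; -0.45 at fixed GC content). The median ratio was -0.99 in the 20% of genes lowest in GC content and 0.62 in the 20% highest.

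**Figure D3:**
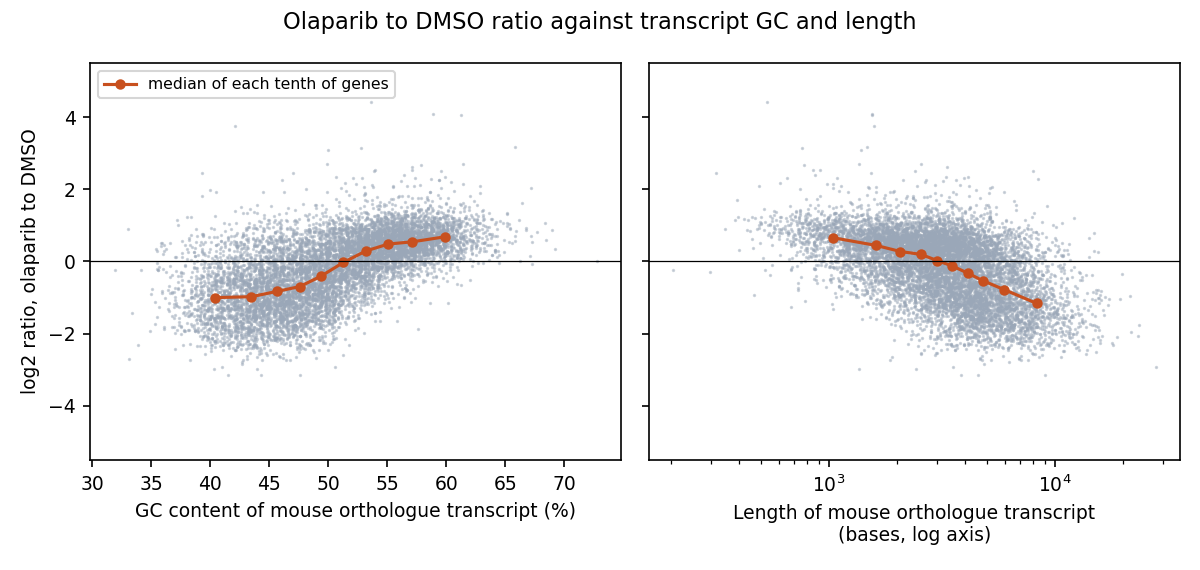
Log2 ratio of olaparib to DMSO for each of 9035 human genes against the GC content (left, percent) and the length (right, bases on a log axis) of the mouse orthologue's transcript, with medians of 10 equal bins of genes in orange. Ratios climb with GC content (rho 0.65) and fall off with length (rho -0.51).

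Of 29 measured interferon-stimulated genes, 13 were higher and 1 lower by the size rule, and their median of 0.99 was exceeded by 0 of 10000 matched lists, also when lists were matched on GC content and length. The chemokine CCL5 went from 5 to 113 counts (4.41), CXCL11 from 8 to 106 (3.74) and the antiviral OASL from 585 to 3699 (2.84). Of 22 NF-kB and secreted inflammatory genes, 8 were higher and 1 lower, with a median of 1.05 that 0 of 10000 lists reached under either matching. IL1B went from 0 to 28 counts, at least 10.6-fold higher, and the neutrophil growth factor CSF3 (2.08), the chemokine CCL20 (2.07) and the receptor TNFRSF9 (2.32, from 3 to 17 counts) were higher; the ratios of CCL5 and TNFRSF9 shrank by more than 1.5 times with a pseudocount of 5. Of 15 genes of cytosolic DNA sensing and class I antigen presentation, 6 were higher and 1 lower (median 0.97, percentile 99.99): the immunoproteasome subunit PSMB9 was at 1.74, HLA-C at 1.40 and HLA-B at 1.39, and the sensing kinase TBK1 at -1.47. All 10 measured histone genes had positive ratios, 4 of them past the size rule (median 1.16, above all 10000 lists), led by H2BC11 (1.77). Of 46 oxidative phosphorylation genes, 12 were higher and 2 lower (median 0.75, above all 10000 lists), with COX5B at 1.47 and UQCRC2 at -1.44. For these last 3 lists, 66.7%, 0% and 76.1% of members had an orthologue value, under the 80% set for a check, so the check on GC content and length is void.

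Of 31 homologous recombination and Fanconi anaemia genes, 14 were lower and 1 higher, with a median of -0.92 (percentile 0.44). RBBP8, which starts end resection, stood at -2.92 (308 to 35 counts), the helicases BLM and BRIP1 at -2.73 and -2.27 and FANCB at -2.16. Of 29 other repair and checkpoint genes, 13 were lower and 1 higher (median -0.78, percentile 0.56), led by TOPBP1 (-2.73), the Ku subunit XRCC5 (-2.54), the checkpoint kinase ATR (-2.35) and RIF1 (-2.15). PARP1, the drug's target, stood at -0.47 (2130 to 1360 counts). Of 27 G2/M and mitosis genes, 11 were lower and 0 higher (median -0.50, percentile 0.40), among them BUB1B (-2.16), DLGAP5 (-2.14) and KIF23 (-2.04). Among lists matched also on GC content and length, the percentiles of these 3 lists were 5.76, 9.84 and 26.82, so none stood apart. Of 29 G1/S and replication genes, 3 were higher and 4 lower (median -0.01, percentile 25.92), with POLA1 at -1.96 and RRM1 at -1.73.

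**Figure D4:**
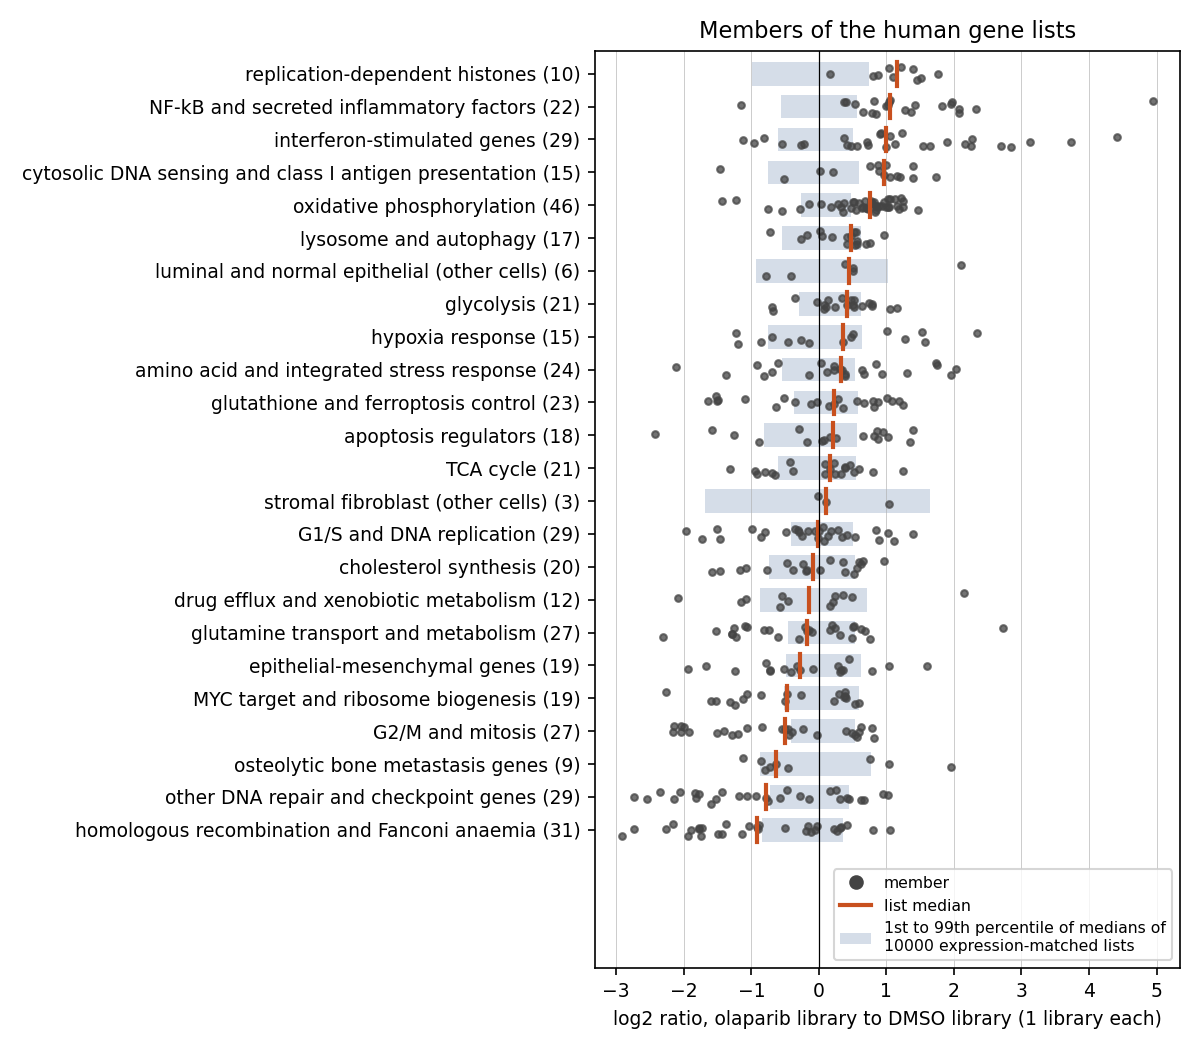
Log2 ratios of olaparib to DMSO for every measured member of 24 human lists, with a bar at each median and a band from the 1st to the 99th percentile of medians of 10000 expression-matched lists. The interferon list lies above its band at 0.99 and the homologous recombination list below its band at -0.92.

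Glutamine genes of the tumour line leaned lower without standing apart: of 27 measured, 0 were higher and 8 lower among those ranked (median -0.18, percentile 9.49; 49.82 when matched on GC content and length). The glutamine transporters SLC38A1 (2423 to 431 counts, -2.31), SLC38A2 (2740 to 992, -1.28) and the cystine transporter SLC7A11 (524 to 159, -1.53) were lower. GLUL stood at 0.32 (960 to 1055 counts) and SLC1A5 at 0.52 (1706 to 2160). Of 23 glutathione and ferroptosis genes, 4 were higher and 5 lower (median 0.23, percentile 51.35); the lipid peroxidase GPX4 stood at 1.08 and the transferrin receptor TFRC at -1.64. Of 24 integrated stress response genes, 4 were higher and 2 lower (median 0.33, percentile 88.01), with CEBPB at 2.03 and the tRNA exporter XPOT at -2.11. Glycolysis (2 of 21 higher, 0 lower; median 0.41, percentile 80.48; 57.96 with quantile normalization) and the TCA cycle (1 higher and 1 lower of 21; median 0.17, -0.01 on the deposited scale; percentile 60.73) did not stand apart.

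Of 9 osteolytic bone metastasis genes, 6 had negative ratios (median -0.63, percentile 3.76, and 3.10 when matched on GC content and length). Of the 7 ranked, 2 were higher and 0 lower by the size rule. The median of these 7 was -0.45, and it turned to 0.51 with the GC and length trend removed. IL11 went from 189 to 648 counts (1.95) and CSF2 from 751 to 1366 (1.04). ADAMTS1 (-0.85, 60 to 29 counts) and OPN3 (-1.12, 43 to 17 counts) were too low to be ranked. PTHLH, the parathyroid hormone-related factor of osteolysis, had 10 and 2 counts (-1.73, interval -5.37 to 0.09), so a change was not detectable at this depth. The drug efflux gene ABCB1 had 1 and 0 counts and SLFN11, linked to PARP inhibitor sensitivity, 2 and 0, both under the floor. MYC stood at 0.23 (0.05 on the deposited scale). Apart from genes given above, the highest ratios were in the keratin KRT17 (4.08, 13 to 209 counts), the stress cytokine GDF15 (4.07, 168 to 2502 counts), the cystatin CST1 (3.73), C1QL1 (3.18), the cholesterol hydroxylase CH25H (3.10), HES4 (2.98), the uncharacterized AL645608.7 (2.80, 18 to 116 counts) and ADAP1 (2.70). The lowest were in HSP90AA2P (-3.56), USPL1 (-3.15), the kinase STK38L (-3.15), SAMD12 (-3.14), DNTTIP2 (-2.99), APOOL (-2.97), the nuclear envelope gene SYNE1 (-2.94), ZNF638 (-2.83), the kinesin KIF15 (-2.83), PPIP5K2 (-2.80) and the tight junction gene TJP1 (-2.74). TNFSF11, which encodes RANKL, was not analysed here for the tumour line. Of 3 fibroblast markers measured, only 1 was ranked and it did not pass the size rule, with ACTA2 at 1.04 (11 to 21 counts) among the unranked (median 0.10, -0.08 on the deposited scale; percentile 54.59). Of 6 luminal markers, 3 were ranked and 0 of them passed, with FOXA1 at 2.10 (5 to 22 counts) among the unranked (median 0.44, percentile 72.91). Only 2 leukocyte markers were measured, CSF1R (6 to 17 counts) and CD74 (19 to 48).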

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

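Leaving out macrophage library 1 with osteoclast library 2, leaving out ribosomal RNA-like features, matching human lists on GC content and length, quantile normalization for human lists, and removing the GC and length trend were chosen only after results were seen. The other settings were chosen before the data were examined. Of the 143 named mouse genes, 3050 values kept direction and side of the threshold, 45 (14 genes) lost a call, 27 (13 genes) gained one and 9 (5 genes) reversed. Without each library in turn, 3975 to 4367 genes were higher and 3747 to 4151 lower, with 10 to 11 lists higher and 1 lower; with macrophage 1 and osteoclast 2 both left out, 4403 and 4161. DESeq2 gave 4055 and 3761. A mean count of at least 50 left 793 genes higher and 533 lower by 1 log2, as fewer genes were tested. The deposited scale gave 1800 genes higher, and equal totals 2625 higher, 6445 lower and 1317 lower by 1 log2. The median gene shifted by -0.19 and -0.22, which does not account for the fewer calls on the deposited scale. There all libraries were given the same size. Differences in total counts within a group, such as 16743849 and 21386319 for macrophage libraries 1 and 2, then count as spread between replicates. Whether this alone gives the fewer calls was not tested. Slc3a2 turned to -0.001 on the deposited scale and -0.032 with equal totals, and Slc38a2 to -0.016 with equal totals. Leaving out single libraries took Fn1 from -3.94 to 0.283, Col1a2 from -3.687 to 1.13 and Col1a1 from -3.533 to 1.188, the positive values without macrophage library 1; with osteoclast 2 also left out they were 0.008, 0.374 and 0.675. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 3 lower; fry does not compare a list with other genes.

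The replicate number as a block gave 4237 genes higher and 4114 lower, lost no list call and added the neutrophil list. Same-numbered libraries correlated by 0.035, 0.038 and 0.096 in their deviations, and the highest correlations with another number were 0.051, 0.03 and 0.025. These values show no strong pairing by number. With 3 libraries per group they cannot exclude shared animals or days.

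Of the 155 named human genes, 847 values stayed within their counting interval, 77 (49 genes) moved beyond it and 0 past the size rule turned sign. Below the size rule, CAD turned from 0.16 to -0.022 and COL1A1 from 0.10 to -0.08 on the deposited scale. A mean of at least 10 gave 1371 genes higher, and of at least 200 gave 467 higher and 1169 lower, since other numbers of genes were ranked; a ratio of at least 1.5 gave 158 and 1036. The deposited scale gave 448 higher and quantile normalization 1262; the cause was not tested. Lists matched on GC content and length left 3 above and 1 below among 22, with 3 lists void, 3 lost and MYC targets and hypoxia gained. Quantile normalization kept all 8 lists that stood apart and gained MYC targets. With the trend removed, 525 genes were higher and 525 lower, against 663 and 1973 of the same genes before. Depth limits genes near the floor, such as PTHLH, ABCB1 and SLFN11.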

Other observations

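The S100a9 test and the stromal test were chosen only after the result was seen. The criteria of the other tests were written before their own values were computed, but after the data had been opened.

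Some genes of signalling to bone-forming cells also differed in osteoclasts, but camera did not call their list with TMM. Of 13 tested osteoclast-derived coupling factors, 9 rose and 4 fell, also adjusted over the list alone but 6 and 4 on the deposited scale (camera adjusted p = 0.0903; the list was called on the deposited scale and with equal totals). The cytokine Lif rose by 5.46 log2 and the membrane ligand Efnb2 by 3.68 (6.43 and 4.92 without macrophage library 1). The sphingosine kinase Sphk1 and the secreted Cthrc1, with 3 macrophage counts each, had ratios of 45.5 (95% counting interval 15.2 to 224) and 22.4 (7.29 to 112), and the bone morphogenetic protein Bmp2 fell by 1.57. Of 22 lysosomal genes, 9 rose and 8 fell, the same adjusted over the list alone but 4 and 8 on the deposited scale, 8 and 12 with equal totals and 6 and 14 after quantile normalization (median -0.02, mean 0.03, camera adjusted p = 0.943): the protease genes Ctsl and Ctsz rose by 1.06 and 1.02, and the membrane protein gene Scarb2 fell by 1.02. Of 20 cholesterol synthesis genes, 4 rose and 9 fell, also adjusted over the list alone but 2 and 9 on the deposited scale and 2 and 11 with equal totals (median -0.04, camera adjusted p = 0.471), with Mvd at 0.70 and Dhcr7 at -0.51.

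In the olaparib library, the angiogenic factor VEGFA went from 1899 to 4824 counts (1.53) and the lipase inhibitor ANGPTL4 from 49 to 222 (2.34), within a hypoxia list of 15 genes with 4 higher and 2 lower (median 0.36, percentile 84.78; 99.55 when matched on GC content and length, 65.28 with quantile normalization, and 49.06 with a mean of at least 50). Of 19 MYC target and ribosome biogenesis genes, 0 were higher and 7 lower, led by NOP58 (-2.26) and DDX21 (-1.60). Their median was -0.47, at percentile 1.28, with 0.39 when matched on GC content and length and 0.84 with quantile normalization. Of 19 epithelial-mesenchymal genes, 1 was higher and 3 lower (median -0.28, percentile 4.81; -0.08 and 15.35 with a mean of at least 50), with ZEB1 at -1.94 and TGFB2 at -1.67. Of 18 apoptosis regulators, 3 were higher and 3 lower (median 0.21, percentile 76.34), with BIRC2 at -2.43 and PMAIP1 at 1.40. Of 12 efflux and xenobiotic genes, 0 were higher and 1 lower among those ranked, with ABCC4 at -2.08. Their median was -0.15, at percentile 30.23, and at 95.28 when matched on GC content and length. Of 20 cholesterol synthesis genes, 0 were higher and 3 lower (median -0.08, 0.10 with quantile normalization and 0.01 with a mean of at least 50; percentile 37.94), and of 17 lysosome and autophagy genes 0 were either (median 0.47, percentile 91.32).

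The 6 mouse libraries can be split into 3 and 3 in 10 ways. Only the real split, 1 of 10, gave as many genes, 8443 against 0 for the highest other; for lists it was again 1 of 10, 11 against 10. With 10 splits a share under 0.05 cannot be reached. Splits that mix the groups called 8 to 10 lists with 0 genes. Each such split sets 2 libraries of a group against 1, so those calls may hold part of the real difference, and the 8 to 10 lists were not taken apart further.

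Antimicrobial genes such as Lcn2, S100a8 and Mmp8 rose in osteoclasts, which might come from neutrophils in those cultures. Without Lcn2 the median of the 3 tested neutrophil genes was 6.39 log2, above the 1 log2 of the criterion written beforehand for neutrophils. That criterion also asked for higher S100a8 and S100a9, and S100a9 had 0 macrophage counts and 1 osteoclast count. S100a8 and Mmp8, part of the rise to be explained, set this median, while Csf3r fell. S100a9, which neutrophils hold in abundance together with S100a8, had 0.107% of the 935 counts of S100a8 (95% interval 0.0027 to 0.597%). This is below the 10% that the test chosen afterwards asked of neutrophils. That test was set with the counts known. No library held more than 1 count of S100a9, so whether the gene could be counted here is not known. The test therefore does not decide about neutrophils. Elane, Mpo and Cxcr2 had 1, 1 and 0 osteoclast counts. The granule gene Camp went the other way, with 3 macrophage and 26 osteoclast counts. Whether Lcn2, S100a8 and Mmp8 came from neutrophils or from osteoclasts or their precursors stays open. Expression by osteoclasts or their precursors was not tested.

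Macrophage library 1 held far more stromal matrix transcripts than the other macrophage libraries, including 102 CPM of Col1a1, 82.7 of Col1a2 and 207 of Fn1. Of the tested stromal genes, 88.9% were at least 4 times higher there than in each of the other macrophage libraries. That share was set after the pattern was seen and restates it, so the source, carried-over stromal cells or a differently prepared sample, stays open.

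The olaparib to DMSO ratios followed sequence features over very many genes, with a rho of 0.65 for GC content, -0.45 for transcript length at fixed GC content and -0.29 for genomic span at fixed GC content and length. A technical difference between the 2 libraries, such as in RNA fragmentation or amplification, might give such trends: between mouse libraries of the same group, rho reached 0.47 in size for length, near the -0.51 of olaparib to DMSO, in a pair with osteoclast library 2, but only 0.24 for GC content. Less transcription along long genes under the drug could give the olaparib trends of length and span. Whether it could also give that of GC content was not tested. The rho of GC content was 0.62 at fixed transcript length, and a value at fixed genomic span was not computed. Lower homologous recombination genes could follow from the trend, since the list lay at percentile 5.76 among lists matched on expression, GC content and length. With the trend removed, the median of its ranked members was still -0.46, so the trend was not shown to account for all of it. The interferon list stayed at percentile 100 among such lists, so the trend alone does not account for it; with 1 library per condition, technical and drug effects were not separated, and a response of the interferon genes to olaparib remains an open hypothesis.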
